A study of Homo sapiens with 3 samples.

How the data were processed

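RNA was measured in 3 cultures of the human breast cancer line MDA-MB-231, with 1 library for each of 3 groups, taken from the titles of the samples. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from 1 ug of total RNA with a stranded mRNA kit. The authors deposited a single table of RPKM values (reads scaled by exonic length and library size) for the 3 libraries. Per the submitters' processing notes, Bowtie 0.12.2, featureCounts and Subread 1.5.1 were used, and the genome builds mm8 and GRCh38 are named, without their roles. The gene annotation, the counting settings and the denominator of the RPKM values are not given in the sources used here.

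The table has 34014 rows, of which 31538 were above 0 in at least 1 library. Names of 27 rows had been turned into dates, 18 of them past the filter on low values, and such rows are named nowhere. Of all rows, 24006 (70.6%) matched 1 gene of GENCODE 29 by name, and of the 14107 rows past the filter 11736 (83.2%) did. Because an RPKM value is a whole number of reads divided by exonic length and library total, reads were recovered from the low values. Of 22639 matched rows above 0, 20499 (90.5%) gave whole reads in all 3 libraries within 0.02 of a read, against 0.0064% by chance. That chance share takes the 3 values as independent and above 0, and it is higher for rows at 0 in a library. For rows that gave no whole reads in this way the length was solved from the values. Reads were obtained for 13795 (97.8%) of the rows past the filter. The library totals were 14954648, 17000245 and 15905713 for control, FMF_L and FMF_H, and the recovered reads summed to 101%, 101% and 101% of them, so some reads may count for more than 1 gene or some lengths may be off. In the control, 1 RPKM on a 1 kb gene stands for 14.95 reads. RPKM values do not sum to the same figure across libraries (391215, 408534 and 818001), so short and abundant transcripts such as mitochondrial ones raise the sum.

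The gene lists, comparisons, settings and the rule for naming genes were fixed before the data were examined. For each of the 3 comparisons the difference of log2(RPKM + 1) was taken per gene among genes with a mean of at least 1 RPKM over the 3 libraries, and a gene was called higher or lower at a difference of at least 1. No p-value was computed. For named genes the ratio of recovered reads per library total was given with its exact 95% Clopper-Pearson interval, which covers counting error only. For 41 gene lists and 6 lists of cell type markers, the median difference of measured members was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to lie apart below percentile 0.5 or above 99.5, and lists with fewer than 5 measured members were given by member, without a median. Members higher or lower by at least 1.5-fold on the same scale were counted. The text names the 10 genes with the largest positive and the 10 with the largest negative difference from the control, 5 and 5 for FMF_H against FMF_L, the TAIRE list, and up to 4 members of each other list with the largest difference. Clones, small RNA genes and pseudogenes were skipped in the ranking by the form of their names, which left in the pseudogene HLA-U and the vault RNA gene VTRNA1-2. Some genes that the rule names are not reported here. Genes outside this rule are said to be chosen after their values were seen.

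Because both treated libraries were compared with the same control, the correlation and overlap of their differences were set beside 100 simulations of unchanged libraries that share the control, over the 13792 genes that could be simulated. Alternatives were pseudocounts of 0.1 and 5, no filter and a minimum mean of 5 RPKM, median-ratio and upper-quartile scaling, rescaling each library to the same sum (TPM), leaving out mitochondrial genes, a threshold of 1.5-fold, an added interval criterion, and lists without their member of largest difference. Restricting to protein-coding genes, to genes with at least 300 recovered reads, filtering on the 2 libraries compared and random lists matched also on exonic length were chosen after the data were seen.

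The procedure was tested on simulated data. For FMF_L against control, genes 8-fold higher or lower were called in 100% of cases, 4-fold higher in 97.4%, 4-fold lower in 83.8% and 1.5-fold higher in 0%, while 0.563% of 11894 unchanged genes were called. For FMF_H against control the shares were 100% at 8-fold, 100% at 4-fold higher, 95% at 4-fold lower and 2.5% at 1.5-fold higher, with 0.513% of 11890 unchanged genes called. The simulated libraries were drawn from the means of the control with few genes changed. They thus held no shift of the median gene like that of FMF_H (-0.94). The shares for FMF_H cover counting error, not the dependence of its calls on scaling. Exact intervals held the true ratio for 95.4% and 96.4% of 500 unchanged genes. Of 100 random lists, 1 and 0 lay apart, and all 100 lists raised by 0.5 did. Those shares hold for the simulated libraries only. In FMF_H against control, random lists matched to the 20 unfolded protein response genes ran from -1.42 to 0.40 (median -0.47). A shift of 0.5 thus need not lie apart there. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.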

Results

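RNA sequencing measured gene expression in MDA-MB-231 cells, a human triple-negative breast cancer line with mesenchymal features that is used as a model of aggressive breast cancer. The cells were either controls or treated with FMF-04-159-2, a compound known from the literature as a covalent inhibitor of CDK14 and its close relatives. Those kinases form the TAIRE family, bind cyclin Y and have been linked to Wnt signalling and mitosis. Of the 3 libraries, 1 was a control, 1 came from cells labelled FMF_L and 1 from cells labelled FMF_H. The labels do not say what L and H stand for, so they are used here as names. With 1 library per group, no difference has a replicate check, and each statement compares libraries, not conditions. The intervals cover counting error alone. The read totals that underlie the RPKM values were 14954648 in the control, 17000245 in FMF_L and 15905713 in FMF_H, and 14107 genes had a mean of at least 1 RPKM over the 3 libraries. Differences are given on the log2(RPKM + 1) scale, which understates the change of genes with low values. Positions refer to the GRCh38 human genome with GENCODE 29 genes.

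The presumed targets of the compound were examined first. CDK14, on chromosome 7 from 90466424 to 91210590, had 1.75 RPKM in the control, 1.76 in FMF_L and 0.267 in FMF_H. The ratio of its reads per library total was 1.01 for FMF_L over control (exact 95% interval 0.82 to 1.24) and 0.152 for FMF_H over control (0.0992 to 0.226). CDK17, on chromosome 12 from 96278261 to 96400560, behaved alike in FMF_H, with 3.23 RPKM in the control, 3.82 in FMF_L and 0.49 in FMF_H. CDK16, on chromosome X from 47217860 to 47229997, was the most abundant kinase of the family, at 19.7, 21.4 and 10.96 RPKM in the same order. Cyclin Y itself, CCNY on chromosome 10 from 35247025 to 35572669, had 9.56, 12.05 and 5.16 RPKM. Its relative CCNYL1, on chromosome 2 from 207711540 to 207761839, had 10.98, 11.6 and 4.82 RPKM. CDK15, CDK18 and CCNYL2 stayed below 1 RPKM in each library. In FMF_L none of the 5 measured members of this list differed from the control by 1.5-fold or more. In FMF_H all 5 were at least 1.5-fold lower, with a median of -1.04 (0.13 relative to the median gene), at percentile 46.6 of random lists of equally expressed genes. After scaling to the median gene, CDK16, CCNY and CCNYL1 lay above the control (0.46, 0.40 and 0.13), whereas CDK14 and CDK17 stayed below it (-0.61 and -0.81). Exons of CDK14, CCNYL1 and CCNYL2 share bases with other genes, so their values are uncertain.

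FMF_L against control asks what the treatment labelled L changed. The transcriptome of FMF_L stayed close to that of the control, and genes of mitosis stood out among those with less RNA. AURKB, a kinase of the chromosomal passenger complex, on chromosome 17 from 8204733 to 8210600, led the lower genes with 48.5 RPKM in the control and 15.3 in FMF_L, a read ratio of 0.316 (exact 95% interval 0.287 to 0.348). Among the higher genes were PLAT, which encodes tissue plasminogen activator (31.3 and 96.5 RPKM, read ratio 3.08, interval 2.96 to 3.21), and the carboxypeptidase gene CPA4 (2.21 and 10.3 RPKM, read ratio 4.65, interval 3.86 to 5.65). In all, 112 genes were higher and 144 lower by at least 1 on the log2 scale, and 90.7% of the 14107 genes lay within 1.5-fold of the control. Counting error alone gave on average 30.6 higher and 27.3 lower genes in simulations of an unchanged library. After median-ratio scaling 103 genes were higher and 81 lower, so that the higher genes made up 56.0% of the called genes in place of 43.8%. The counts were 274 and 368 with a pseudocount of 0.1, 16 and 19 with a pseudocount of 5, and 25 and 60 (29.4% higher) among protein-coding genes alone, a restriction chosen after the data were seen.

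Of the 36 measured G2/M and mitosis genes, 9 were at least 1.5-fold lower in FMF_L and none was 1.5-fold higher. The median of the list was -0.47, below each of the 10000 random lists (percentile 0). TOP2A, the DNA topoisomerase of proliferating cells, went from 90.8 RPKM in the control to 41.0 in FMF_L, CDC20, an activator of the anaphase-promoting complex, from 76.3 to 38.5, and the kinetochore gene NUF2 from 28.1 to 14.5. The list of G1/S and DNA replication genes had a smaller shift, with a median of -0.23 (percentile 0.22) and 3 of 31 members at least 1.5-fold lower. The thymidine kinase gene TK1 (70.2 and 44.3 RPKM) and the ribonucleotide reductase subunit gene RRM2 (56.3 and 35.7) were among its most shifted members. Without the member of largest difference the percentile of this list was 0.71 and it no longer lay apart from random lists. PSRC1, a microtubule regulator (35.3 and 11.9 RPKM), and ASF1B, a histone chaperone of replicating cells (19.5 and 6.54), were among the 10 genes with the largest negative difference.

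Targets of the hypoxia-inducible factors were higher in FMF_L, with 7 of 17 measured members at least 1.5-fold higher, none lower, and a median of 0.39 (percentile 100). NDRG1 had 6.88 RPKM in the control and 15.7 in FMF_L, the prolyl hydroxylase gene P4HA2 3.98 and 7.96, the lysyl oxidase gene LOX 2.05 and 4.49, and the mitophagy gene BNIP3 25.6 and 45.1. Extracellular matrix and protease genes had a median of 0.35 (percentile 100), with 5 of 22 at least 1.5-fold higher. Besides PLAT and LOX these included the collagenase gene MMP1 (471 and 951 RPKM) and ADAMTS1 (22.8 and 45.6). The ATF4 target list had a median of 0.18 (percentile 99.9; 98.4 with a minimum mean of 5 RPKM), and 4 of its 24 measured members were at least 1.5-fold higher. SLC3A2 and SLC7A5, which together form an amino acid transporter, had 35.3 and 64.8 RPKM in the control and 59.6 and 106 in FMF_L. The 13 mitochondrially encoded mRNA genes had a median of 0.24 at percentile 99.53, so close to the limit that it was lost with a pseudocount of 0.1 (percentile 99.4), after rescaling each library to the same sum (99.4) and without the member of largest difference (99.3). Reads of mitochondrial genes, transfer and ribosomal RNAs included, made up 6.94% of the control total (exact 95% interval 6.93 to 6.95) and 8.04% of the FMF_L total (8.03 to 8.06).

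Cytoplasmic ribosomal protein genes were slightly lower in FMF_L, with a median of -0.19 over 38 genes (percentile 0.08) and none beyond 1.5-fold. The list fixed as nuclear-retained noncoding RNAs had a median of -0.48 (percentile 0.01), and 4 of its 11 measured members were at least 1.5-fold lower. The snoRNA host genes SNHG5 (15.9 and 9.09 RPKM), SNHG1 (12.3 and 7.13) and GAS5 (25.6 and 16.7) and the long noncoding RNA TUG1 (14.5 and 8.85) led this list. The spliced RNAs of these host genes are known to be mainly cytoplasmic, unlike the name of the list. The Wnt lists did not stand apart in FMF_L. The 7 measured Wnt/beta-catenin targets had a median of 0.14 (percentile 89.5), with CCND1 at 117 and 84.9 RPKM and LEF1 at 2.18 and 3.25, and the 25 receptors and signal components had a median of -0.06 (percentile 37.8). Of the 18 other cyclin-dependent kinase and inhibitor genes measured, 4 were at least 1.5-fold lower (median -0.02, percentile 61.5), among them CDK4 (37.7 and 17.3 RPKM) and CDK2 (33.1 and 17.5). Exons of CDK4, CDK2, NUF2, ASF1B, P4HA2, LOX, MMP1, SLC7A5, GAS5, TUG1, CCND1 and LEF1 overlap genes on the opposite strand, as do those of HJURP, JUNB, MAP7D1, IER2, IER3, IL6, HLA-B and WIPI1 named for FMF_H. Whether strand was used in counting is not given in the sources used here, so these values are uncertain. RRM2, SNHG1, SNHG5, TUG1, AMOTL2, AXIN2, SRSF4, HLA-B and MT-ND4 share exonic bases with genes on the same strand and are uncertain as well.

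Further genes at the top of the ranking were the BMP antagonist gene NOG (26.4 and 70.9 RPKM) and the GDNF receptor gene GFRA1 (0.449 and 2.67). KRTAP2-3, a keratin-associated protein gene on chromosome 17 from 41059240 to 41060114, had 15.5 and 75.2 RPKM, and its neighbour KRTAP2-4 had 2.01 and 8.39. These are near-identical copies that can share reads, so the value of each is uncertain. The antisense genes SYNE1-AS1, DBH-AS1 and ZNFX1-AS1_1 also ranked among the 10 highest, with 110, 185 and 17 reads in FMF_L and 28, 42 and 2 in the control. The first 2 overlap exons of SYNE1 and DBH on the other strand, and no position was matched for the last, so these values are uncertain too. The lower genes further included RAB24 (6.99 and 1.94 RPKM), C19orf60 (12.2 and 4.15), SNAPIN (9.83 and 3.24) and the membrane scaffold gene FLOT1 (54.0 and 21.4). RAB24 and SNAPIN share exonic bases with a neighbouring gene, as does the antisense gene APOBEC3B-AS1 (9.87 and 3.06). The pseudogene HLA-U and the antisense gene CELSR3-AS1 each had 5 reads in the control and 0 in FMF_L, too few for a fold.

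**Figure D1:**
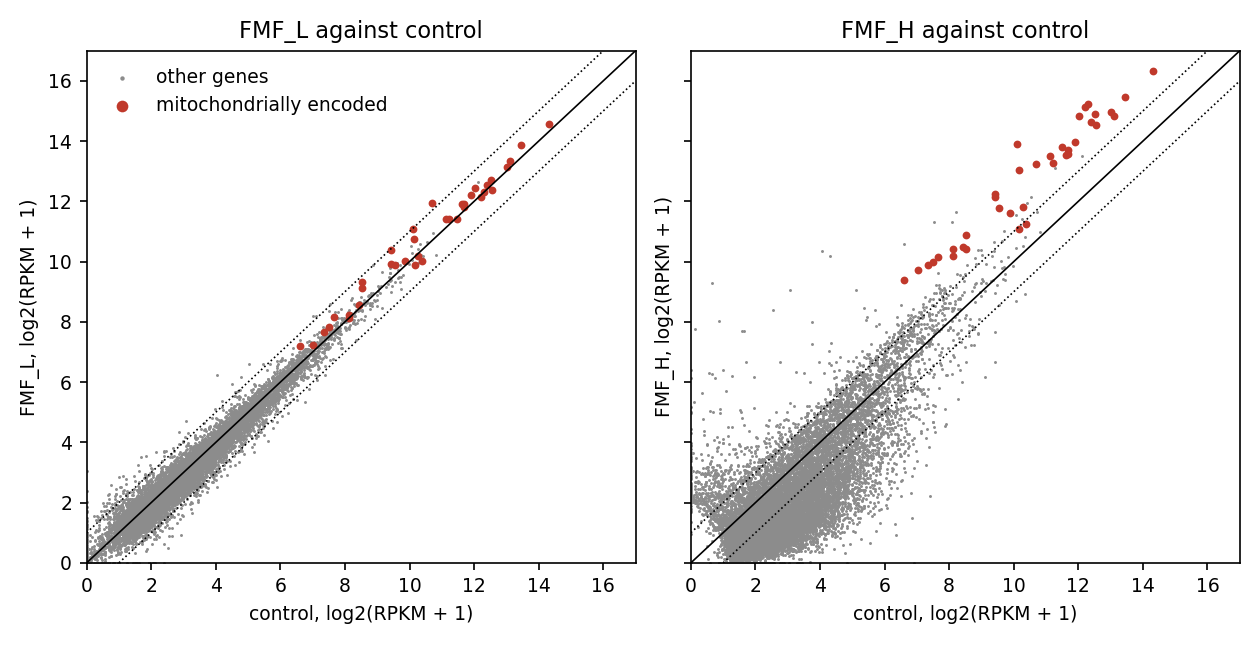
Expression of the 14107 genes in FMF_L (left) and FMF_H (right) against the control, each point a gene, both axes in log2(RPKM + 1), with 1 library per group. The solid line marks equal values and the dotted lines a difference of 1. In FMF_L 112 genes lie on or above the upper dotted line and 144 on or below the lower one, and in FMF_H 915 and 6727, while mitochondrially encoded genes (red) lie above the solid line in FMF_H.

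FMF_H against control asks the same of the treatment labelled H. This library differed far more from the control. Genes of cell division were far lower, whereas immediate early transcription factor genes and mitochondrially encoded genes were much higher. MKI67, which encodes the proliferation marker Ki-67, on chromosome 10 from 128096659 to 128126385, had 168 RPKM in the control and 3.61 in FMF_H, a read ratio of 0.0215 (exact 95% interval 0.02 to 0.0232). JUNB, an AP-1 transcription factor gene on chromosome 19 from 12791496 to 12793315, had 18.8 and 1164 RPKM, a read ratio of 61.9 (interval 56.7 to 67.6). Altogether 915 genes were higher and 6727 lower by at least 1 on the log2 scale, and the median gene lay at -0.94. After median-ratio scaling, which sets the median gene to 0, 3453 genes were higher and 2276 lower, so that the higher genes made up 60.3% of the called genes in place of 11.97%. With a pseudocount of 5 the counts were 449 and 2608, and among protein-coding genes alone 374 were higher. The direction of a gene in FMF_H therefore depends on the reference, and list medians are given both from the deposited values and relative to the median gene.

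Among the 36 G2/M and mitosis genes, 35 were at least 1.5-fold lower in FMF_H and none was higher. Their median was -2.95 (percentile 0), or -1.74 relative to the median gene, where 31 stayed at least 1.5-fold lower and 3 became higher. The mitotic kinase gene AURKA had 78.4 RPKM in the control and 1.46 in FMF_H, the centromere gene CENPF 51.7 and 1.08, and the cyclin gene CCNB1 113 and 4.01. HJURP, the chaperone that deposits the centromeric histone, on chromosome 2 from 233833416 to 233854566, had the largest negative difference of all ranked genes (113 and 1.83 RPKM, -5.34, or -4.26 relative to the median gene). CDCA8 (56.4 and 1.48), FAM83D (29.3 and 0.559) and the nuclear lamina gene LMNB1 (64.5 and 2.82) also belonged to the 10 lowest, as did MAP7D1 (90.6 and 3.64) and CANT1 (25.2 and 0.512). Of the 31 G1/S and DNA replication genes, 27 were at least 1.5-fold lower (median -1.66, percentile 0.16; -0.64 relative to the median gene). That list no longer lay apart with a pseudocount of 5 (percentile 1.79) or a minimum mean of 5 RPKM (2.02). SLBP, which binds histone mRNA, had 67.4 and 3.48 RPKM, UHRF1 43.4 and 2.14, the replication licensing gene CDC6 32.7 and 2.01, and MCM3 88.0 and 11.2.

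The immediate early and AP-1 list had a median of 1.97 (percentile 100), or 3.13 relative to the median gene. Of its 21 measured members 15 were at least 1.5-fold higher and 5 lower. EGR1 had 4.82 RPKM in the control and 336 in FMF_H, FOS 0.578 and 76.5, and IER2 33.9 and 534. ARC, another immediate early gene, on chromosome 8 from 142611044 to 142614472, had the largest difference of all ranked genes (7.63, or 8.53 relative to the median gene), from 4 reads in the control to 10254 in FMF_H. MYC (43.3 and 282 RPKM) and IER3 (295 and 3241) belong to the immediate early list and to others, MYC also to that of MYC targets. Among members of other lists, the stress-inducible genes GADD45A had 39.8 and 351 RPKM and GADD45B 12.5 and 253. The cytokine genes CXCL3 had 14.6 and 100.04 and IL6 3.98 and 22.8. In the deposited values most members of these lists were lower by at least 1.5-fold. These were 13 of 17 p53 targets (2 higher), 14 of 23 YAP/TAZ targets (4 higher) and 14 of 25 NF-kB targets (8 higher). Relative to the median gene 4 p53 targets were lower and 4 higher, and 12 YAP/TAZ targets lower and 9 higher. On that scale 5 NF-kB targets were lower and 12 higher. KRTAP2-3 (15.5 and 1299 RPKM), KRTAP2-4 (2.01 and 205) and KRTAP2-2 (0.274 and 49.3) ranked among the 10 highest here as well. TMEM88 (1 and 553 reads), the vault RNA gene VTRNA1-2 (3 and 142 reads) and the histone gene HIST1H4C (2 and 182 reads) completed that group. The 13 measured histone genes had a median of 0.63 (percentile 99.9), or 1.97 relative to the median gene, which became -0.29 when each library was rescaled to the same sum. The list no longer lay apart with a minimum mean of 5 RPKM (percentile 98.7) or against random lists of protein-coding genes matched on expression and exonic length (99.4), an alternative chosen after the data were seen. HIST2H2BE had 1.01 and 14.8 RPKM and HIST1H3B 1.30 and 8.11, but the linker histone gene H1F0 had 239 and 23.6.

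Mitochondrially encoded mRNA genes were higher in FMF_H without exception, with a median of 2.02 over 13 genes (percentile 100), or 3.36 relative to the median gene. MT-ND3 had 2237 and 11547 RPKM and MT-ND4 5399.6 and 25344. Reads of mitochondrial genes made up 30.4% of the FMF_H total (exact 95% interval 30.3 to 30.4) against 6.94% in the control. Among lists of nuclear genes, those of lysosome and autophagy (median 0.61, percentile 100), antigen presentation (0.42, percentile 99.9; 99.2 with a minimum mean of 5 RPKM) and nuclear oxidative phosphorylation (0.38, percentile 99.95) lay above random lists. In FMF_L the antigen presentation list had a median of -0.23 (percentile 0.92) and did not lie apart. It came to lie apart under 1 of 10 alternatives, a pseudocount of 5 (percentile 0.38). Relative to the median gene the 3 medians of FMF_H were 1.89, 1.60 and 1.59, but with each library rescaled to the same sum they were -0.39, -0.53 and -0.64. The cathepsin gene CTSB had 39.1 and 92.8 RPKM, B2M, the light chain of the class I complex, 33.6 and 114, HLA-B 193 and 491, and COX6C 82.1 and 284. In the deposited values members went both ways, with 12 of 24 lysosome and autophagy genes at least 1.5-fold higher and 9 lower. Of 20 antigen presentation genes 8 were higher and 3 lower, and of 32 oxidative phosphorylation genes 13 were higher and 6 lower. Among the lower ones were the autophagy gene WIPI1 (10.6 and 0.85 RPKM) and the succinate dehydrogenase gene SDHA (26.5 and 2.89). Relative to the median gene 15 lysosome and autophagy genes were higher and 2 lower. For antigen presentation these counts were 17 and 0, and for oxidative phosphorylation 27 and 2.

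Lists below random lists in FMF_H, besides those of the cell cycle, were YAP/TAZ targets (median -1.49, percentile 0.16), splicing factors (-1.34, percentile 0.14) and MYC targets with ribosome biogenesis genes (-1.29, percentile 0.16). Relative to the median gene their medians were -0.63, -0.06 and 0.00. AMOTL2 had 36.3 RPKM in the control and 3.75 in FMF_H, SRSF4 42.3 and 3.37, SRSF3 43.4 and 5.25, WDR43 55.9 and 4.54, and the lactate dehydrogenase gene LDHA 154 and 8.42. Against the random lists matched on exonic length none of the 3 lay apart (percentiles 0.94, 2.67 and 0.85), and with a pseudocount of 5 the first 2 did not (5.35 and 0.86). Of the 25 Wnt receptors and signal components, 24 were at least 1.5-fold lower (median -1.64, percentile 0.50, on the limit), and 16 lower and none higher relative to the median gene (median -0.76). This list came to lie apart under 5 of 10 alternatives (percentiles 0.26 to 0.485), among them no filter and upper-quartile scaling. Its members included VANGL1 at 5.56 and 0.0902 RPKM, WNT5B at 8.61 and 0.716 and AXIN1 at 7.14 and 0.462. The 7 Wnt/beta-catenin targets had a median of -0.95 (percentile 10.2), or 0.31 relative to the median gene, with AXIN2 at 1.71 and 0.277 RPKM and CCND1 at 117 and 57.3. The 18 other cyclin-dependent kinase and inhibitor genes had a median of -1.02 (percentile 49.6), or 0.00 relative to the median gene. CDK7 had 12.4 and 0.832 RPKM, whereas the inhibitor gene CDKN1C had 0.181 and 7.03. The list medians that stood apart in FMF_L for hypoxia, the ATF4 targets and matrix genes did not do so in FMF_H (-0.64, -0.62 and 0.30 at percentiles 84.6, 81.3 and 99.47), nor did ribosomal protein genes (0.66, percentile 97.9) and nuclear-retained noncoding RNAs (-0.05, percentile 97.3). Relative to the median gene these 5 medians were 0.12, 0.46, 1.42, 1.98 and 1.24, so that the direction turned for hypoxia, the ATF4 targets and the nuclear-retained RNAs. With each library rescaled to the same sum it turned for the matrix (-0.71) and ribosomal protein genes (-0.40). Against the lists matched on exonic length the matrix genes (percentile 99.97) and ribosomal protein genes (99.76) lay apart, the latter also without a filter (99.86).

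**Figure D2:**
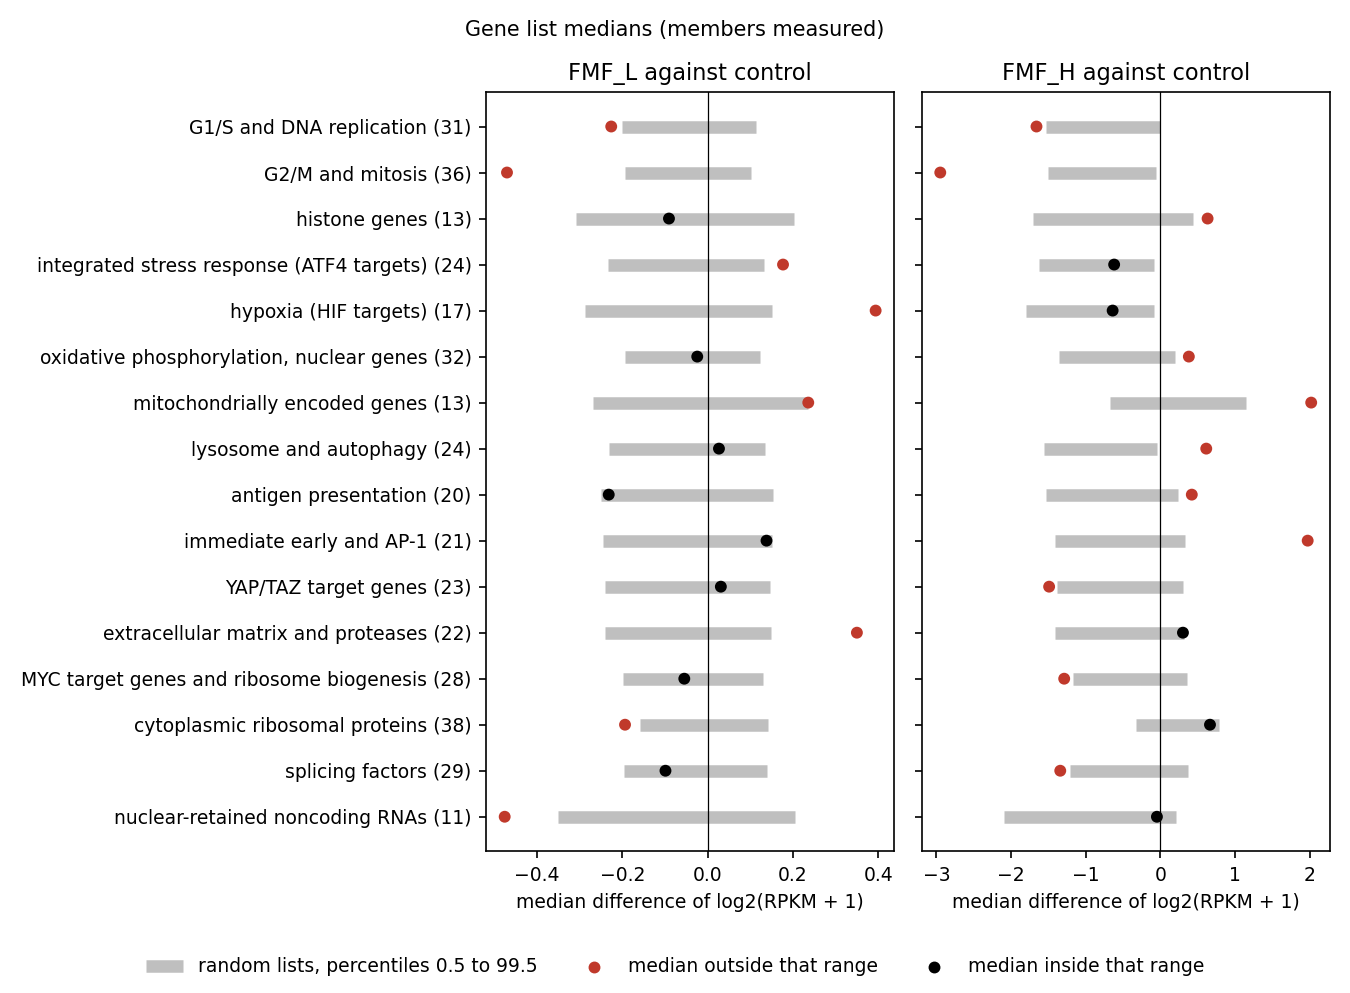
Median difference from the control of log2(RPKM + 1) for the 16 gene lists that lay outside the range of random lists in at least 1 treated library, with the number of measured members in brackets, for FMF_L (left) and FMF_H (right); the scales of the axes differ. Grey bars span the range of 10000 random lists matched on expression beyond which a list was said to lie apart, red points lie outside and black points inside it. The G2/M list lies at -0.47 in FMF_L and -2.95 in FMF_H, and the immediate early list at 1.97 in FMF_H.

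**Figure D3:**
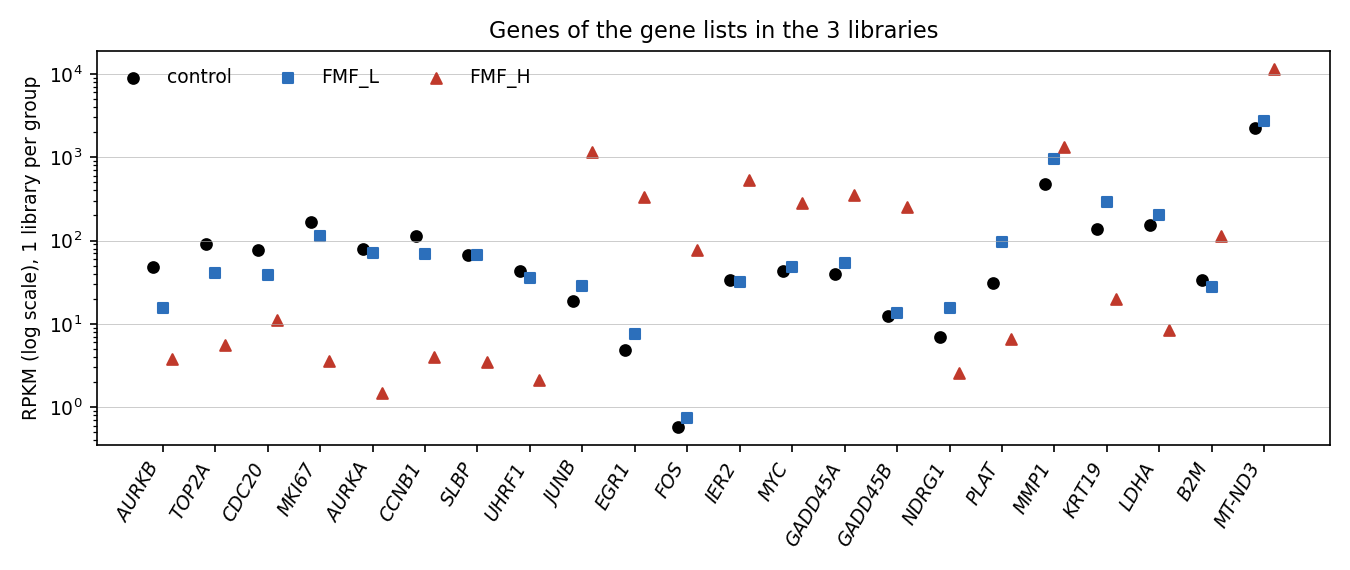
RPKM values (log axis) of 22 list genes in the control (circles), FMF_L (squares) and FMF_H (triangles), 1 library per group, with no error bars because there are no replicates. MKI67 has 168, 112 and 3.61 RPKM, EGR1 4.82, 7.61 and 336, and PLAT 31.3, 96.5 and 6.60.

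The difference between FMF_H and control also varied with the genomic span of protein-coding genes. Among the 1019 genes with the shortest span, up to 5.34 kb, the median was -0.03 and 20.6% were lower by at least 1. Among the 1019 genes with the longest span, the median was -1.27 and 63.9% were lower. The group of the next shorter span, from 90.4 kb, had the lowest median (-1.35), with 66.6% lower, so the trend did not run on to the longest genes. These medians were 1.11 for the shortest, -0.49 for the longest and -0.51 for the next shorter group relative to the median gene, so that the shortest group then lay above the control. The 259 protein-coding genes with a single block of exons had a median of 0.14 in FMF_H, against -1.06 for the 9931 with more. In FMF_L the medians of the same span groups ran the other way and over a small range, from -0.19 for the shortest to 0.06 for the longest genes. The rank correlation across genes with span, within strata of exonic length and mean expression, was -0.214 in FMF_H and 0.223 in FMF_L, and genes are not independent replicates. These groupings were chosen after the data were seen.

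**Figure D4:**
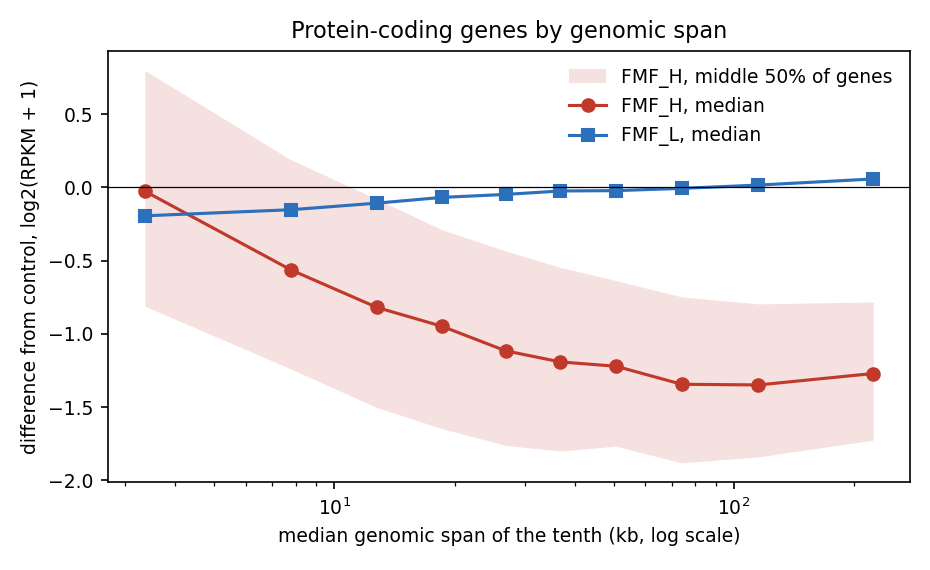
Median difference from the control of log2(RPKM + 1) in 10 groups of 1019 protein-coding genes ordered by genomic span (log axis, median span per group in kb), for FMF_L (squares) and FMF_H (circles), with the middle 50% of genes of FMF_H shaded. The FMF_H medians run from -0.03 in the group of shortest span to -1.27 in the group of longest span, and those of FMF_L from -0.19 to 0.06.

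FMF_H against FMF_L compares the treated libraries with each other and leaves the control out. Cell division genes were again far lower in FMF_H and immediate early genes far higher. In all 1040 genes were higher and 6427 lower in FMF_H, with a median gene at -0.88. After median-ratio scaling 3490 were higher and 2431 lower, 58.9% higher in place of 13.9%. With a pseudocount of 5 the counts were 502 and 2491, and among protein-coding genes alone 479 were higher. ARC (0.275 RPKM in FMF_L and 216 in FMF_H), VTRNA1-2 (0.661 and 100.3), FOS (0.745 and 76.5), JUNB (28.4 and 1164) and EGR1 (7.61 and 336) had the largest positive differences. AURKA (69.8 and 1.46), HJURP (71.0 and 1.83), MKI67 (112 and 3.61), LDHA (201 and 8.42) and MAP7D1 (89.1 and 3.64) had the largest negative ones. The G2/M list had a median of -2.53 (percentile 0), with 33 of 36 members at least 1.5-fold lower, and the G1/S list -1.55 (percentile 0.41), with 23 of 31. MYC targets with ribosome biogenesis genes (-1.46, percentile 0.02) and splicing factors (-1.22, percentile 0.455) were the other lists below random lists. Relative to the median gene these 4 medians were -1.43, -0.55, -0.31 and 0.00. The G1/S list no longer lay apart with a pseudocount of 5 (percentile 2.83), a minimum mean of 5 RPKM (5.635) or without its member of largest difference (0.94). Splicing factors did not without a filter (0.68), with each library rescaled to the same sum (0.56), without mitochondrial genes (0.63) or against the lists matched on exonic length (7.05). In contrast, Wnt receptors and signal components (-1.58, percentile 0.61; -0.81 relative to the median gene) came to lie below under 7 of 10 alternatives, YAP/TAZ targets (-1.32, percentile 0.73; -0.64) under 5 and ERK feedback genes (-1.52, percentile 0.65; -0.45) under 1. Ribosomal protein genes (0.72, percentile 98.7; 1.97) came to lie above under 3 of 10 alternatives and nuclear-retained noncoding RNAs (0.27, percentile 99.3; 1.41) under 3 of 9, and with each library rescaled to the same sum these medians were -0.27 and -0.65. Above random lists lay the immediate early list (1.82), mitochondrially encoded genes (1.78), histone genes (0.94), antigen presentation (0.73), lysosome and autophagy (0.68) and nuclear oxidative phosphorylation (0.42), at percentiles from 99.9 to 100. Relative to the median gene these 6 medians were 2.91, 3.04, 2.13, 1.90, 1.81 and 1.60. With each library rescaled to the same sum the histone median was 0.00 and the last 3 medians were -0.14, -0.27 and -0.52.

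Whether the treated libraries departed from the control in the same genes was examined last. Across the 14107 genes the differences of FMF_L and FMF_H from the control were weakly correlated (Pearson r 0.133, Spearman rho 0.0779, across genes that are not independent replicates). Both share the control library, and unchanged libraries simulated with counting error alone gave an r of 0.528 over 13792 genes, where the observed r was 0.13. The covariance over those genes was 0.053, against 0.0158 on average and 0.0191 at most in the 100 simulations. Of the called genes, 51 were higher in both FMF_L and FMF_H, against 7.26 for independent lists and 12.3 in the simulations. Lower in both were 80, against 68.7 for independent lists and 7.45 in the simulations. For FMF_H the simulations called on average 29.49 genes higher and 28.97 lower, against 915 and 6727 observed. With so few called genes, the simulated overlaps give no reference for the size of the observed ones. After median-ratio scaling 66 were higher in both (25.2 for independent lists) and 22 lower in both (13.1). Part of any excess may come from the shared control, which cannot be split with 1 library. Another 19 genes were higher in FMF_L and lower in FMF_H (53.4 for independent lists), and 6 were the reverse (9.34). After median-ratio scaling these were 6 (16.6) and 16 (19.8), so the order of the groups depends on the scaling.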

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

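The comparison below was chosen only after the values were seen, and so were the 5 genes named in it. They differed from the control by at least 1 in opposite directions in FMF_L and FMF_H, both in the deposited values and relative to the median gene, with at least 300 reads and read ratios whose exact 95% intervals exclude 1. KRT19, an epithelial keratin gene, had 138 RPKM in the control, 290.4 in FMF_L (1.07) and 19.9 in FMF_H (-2.73). INHBB, which encodes an activin subunit, had 23.9, 50.5 (1.05) and 2.45 (-2.85) RPKM. IGFBP1, which encodes an insulin-like growth factor binding protein, had 23.2, 50.2 (1.08) and 2.02 (-3.00) RPKM. C4orf19, whose exons overlap genes on the opposite strand, had 4.297, 10.7 (1.14) and 0.499 (-1.82) RPKM. C19orf33, which shares exonic bases with a gene on the same strand, went the other way, with 139.8 RPKM in the control, 65.7 in FMF_L (-1.08) and 318 in FMF_H (1.18). With 1 library per group, the difference between FMF_L and FMF_H was not tested against replicate error, and no explanation was tested for these genes.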

How the results depend on the processing

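The settings for protein-coding genes, for genes with at least 300 recovered reads, for a filter on the libraries compared and for the pool matched on length were chosen only after the results were seen. Counts below are genes higher and lower, set against 112 and 144 for FMF_L against control, 915 and 6727 for FMF_H against control, and 1040 and 6427 for FMF_H against FMF_L.

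With median-ratio scaling the lower genes of FMF_L were 81, while FMF_H had 3453 and 2276 against control and 3490 and 2431 against FMF_L, and of the named genes lower by at least 1 in FMF_H, CCND1 (0.31), SLC7A5 (0.17), CCNYL1 (0.13) and CDK2 (0.10) lay above the control instead of below. The median gene of FMF_H against control moved from -0.94 to 0.00. With upper-quartile scaling the lower genes of FMF_L were 91, FMF_H had 2652 and 3183 against control and 2758 and 3291 against FMF_L, and the higher genes made up 54.0%, 45.4% and 45.6% of the calls of the 3 comparisons. With each library rescaled to the same sum (TPM), FMF_L had 176 and 308, FMF_H 404 and 10733 against control and 430 and 10239 against FMF_L, with 36.4%, 3.63% and 4.03% higher. There the medians of histone genes (-0.29), nuclear oxidative phosphorylation (-0.64), lysosome and autophagy (-0.39) and antigen presentation (-0.53) fell below 0 in FMF_H against control, as did the last 3 against FMF_L (-0.52, -0.27 and -0.14). These changes follow from the construction, since a scaling shifts each gene of a library by 1 factor.

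With a pseudocount of 0.1 FMF_L had 274 and 368 genes. With a pseudocount of 5, which shrinks each difference, FMF_L had 16 and 19, FMF_H 449 and 2608 against control and 502 and 2491 against FMF_L, and 2 lists lay below random lists in FMF_H against control in place of 5. Without a filter 169 genes were higher in FMF_L. With a mean of at least 5 RPKM, which tests fewer genes, the counts were 46 and 70 for FMF_L, 476 and 3386 for FMF_H against control, and 575 and 3254 against FMF_L. A threshold of 1.5-fold gave 443 and 867 for FMF_L, 1620 higher for FMF_H against control and 1786 against FMF_L. Asking also that the interval of the read ratio exclude 1 left 65 higher genes in FMF_L.

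Among protein-coding genes alone FMF_L had 25 and 60, with 29.4% higher, and FMF_H had 374 higher genes against control and 479 against FMF_L. Among genes with at least 300 reads FMF_L had 32 and 62, and FMF_H 433 higher against control and 546 against FMF_L. Against random lists of protein-coding genes matched on length, 2 lists lay below in FMF_H against control in place of 5, and 9 above in place of 6. Glycolysis (percentile 99.7), ribosomal proteins (99.76), matrix (99.97) and reference genes (99.79) came to lie above and histone genes (99.4) no longer did, and the cause was not tested.

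The correlation of 0.133 between the differences was 0.156 with a pseudocount of 0.1, 0.193 without a filter, 0.0995 with median-ratio scaling, 0.16 with TPM and 0.106 with upper-quartile scaling. Genes higher in both treated libraries, 51 before, were 146 and 6 with pseudocounts of 0.1 and 5, and 22 at a mean of at least 5 RPKM. Genes lower in both, 80 before, were 168, 10 and 37 under those settings, 22 with median-ratio scaling, 208 with TPM and 30 with upper-quartile scaling. Beyond the effect of construction the cause was not tested.

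Of the other values, 1152 list percentiles kept their side of the limits, 35 came to lie outside them and 22 inside. Among list medians 728 stayed within their spread, 354 moved and 7 reversed, where only lists that lay apart and medians of at least 0.005 count as reversed. Another 94 list medians changed sign, among them MYC targets in FMF_H against control and splicing factors in FMF_H against FMF_L, both to 0.00 with median-ratio scaling. For the named genes 1305 values stayed within their counting interval, 579 moved and 4 reversed, where only differences of at least 1 count as reversed. Another 58 values below that changed sign, among them CDK16 (0.46), CCNY (0.40) and CDK4 (1.02) in FMF_H with median-ratio scaling. Without mitochondrial genes the list of mitochondrially encoded genes gives no value. Depth limits genes of low level most, since at 1 RPKM a 1 kb gene has 14.95 reads in the control.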

Other observations

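Tests of few genes taking most reads, of degraded RNA for the trend with genomic span, of precursor RNAs, of RNA selection for the immediate early genes and of an unusual control library were chosen only after the results were seen, as were the RNA classes below.

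Several classes of small or nonpolyadenylated RNA were higher in FMF_H than random lists of genes of like expression. The 63 snRNA loci, genes and pseudogenes of RNA parts of the spliceosome, had a median difference of 1.404 from the control, with 35 higher by at least 1 and 15 lower. Among them the 26 with names of functional genes had a median of 3.32, with 23 higher and none lower, on 91 reads in the control and 3083 in FMF_H. The filter on low values uses the mean of all 3 libraries, so a locus with few control reads can pass through FMF_H alone. That favours higher over lower calls, and how many loci passed in this way was not counted. Replication-dependent histone genes of the HIST1, HIST2 and HIST3 clusters had a median of 1.73 over 41 genes, with 27 higher and 2 lower, and mitochondrial transfer RNA genes 2.51 over 22. Zinc finger genes of the ZNF series went the other way, with a median of -1.17 and 140 of 224 lower. That was only a little below random lists (-1.08 to -0.74). All protein-coding genes had a median of -1.04, with 5280 of 10190 lower. Long intergenic noncoding RNAs had a median of -0.35 over 118 loci. Relative to the median gene the 6 medians other than that of all protein-coding genes were 2.51, 4.296, 2.60, 3.84, -0.48 and 0.55. The direction thus turned for the long intergenic RNAs. In FMF_L all snRNA loci had a median of 0.00 (percentile 85.1) and the histone clusters -0.06 (34.4). The snRNA loci with functional names (0.29, percentile 100; 3 higher by at least 1) and mitochondrial transfer RNA genes (0.33, percentile 100) lay above random lists there too, whereas snoRNA loci (-0.19, percentile 0) and zinc finger genes (-0.12, percentile 0.02) lay below.

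Several lists fixed in advance did not lie apart from random lists. In FMF_L the medians were 0.06 for p53 targets (percentile 90.5), -0.20 for DNA repair (1.25), 0.01 for the unfolded protein response (67.6), -0.01 for chaperones (52.0), 0.12 for glycolysis (96.2), -0.17 for interferon-stimulated genes (3.89), 0.24 for epithelial genes (98.8) and -0.05 for mesenchymal genes (39.8). BRCA1 had 4.21 RPKM in the control and 1.95 in FMF_L, the interferon-induced gene BST2 139.0 and 73.2, the receptor gene AXL 164 and 74.1, and the keratin gene KRT8 97.1 and 169. Exons of BRCA1, AXL and KRT8 overlap genes on the opposite strand, and those of BRCA1 also on the same strand, so their values are uncertain. In FMF_H the medians of the same lists were -0.91 (54.9), -1.35 (2.21), 0.15 (96.6), -0.67 (11.2), 0.44 (95.5), -0.90 (60.5), -1.02 (20.02) and 0.02 (90.1), or -0.07, -0.67, 1.44, 0.49, 1.68, 0.07, -0.09 and 1.32 relative to the median gene. Feedback genes of the ERK pathway had a median of -1.43 in FMF_H (1.73), NF-kB targets -0.71 (70.9), cholesterol synthesis genes -0.76 (86.4) and proteasome genes -0.21 (77.7), or -0.37, 0.40, 0.20 and 1.09 relative to the median gene. Some of these lists lay apart under other settings, namely DNA repair in FMF_L (0.29 against lists matched on exonic length) and in FMF_H (0.37 with median-ratio and 0.29 with upper-quartile scaling), epithelial genes in FMF_L (99.725 with a pseudocount of 5 and 99.54 against matched lengths) and glycolysis in FMF_H (99.7 against matched lengths). For apoptosis regulators, NRF2, LXR, AHR and TGF-beta targets, fatty acid synthesis, the actin cytoskeleton and luminal markers the percentiles ran from 4.78 to 96.9 in FMF_L and from 8.63 to 92.3 in FMF_H. Of the 4 measured metallothionein genes 3 were at least 1.5-fold higher in FMF_L and 2 in FMF_H, or 4 in FMF_H relative to the median gene. In the order control, FMF_L and FMF_H, MT1A had 8.11, 12.9 and 35.6 RPKM, MT1E 26.1, 44.5 and 21.99, MT1X 6.56, 10.7 and 8.79, and MT2A 1477, 1593 and 4552. Of the 4 measured markers of basal breast epithelium 2 were at least 1.5-fold higher in FMF_L, and 1 was higher and 3 lower in FMF_H, or 2 higher and 1 lower relative to the median gene. KRT17 had 0.29, 1.60 and 3.12 RPKM, EGFR 22.6, 23.0 and 2.92, ITGA6 80.9, 122 and 31.8, and LAMB3 132, 186 and 86.3. EGFR, ITGA6, LAMB3 and MT1X share exonic bases with other genes, and metallothionein genes are similar copies that can share reads, so these values are uncertain. Commonly used reference genes had medians of 0.01 in FMF_L (59.97) and 0.53 in FMF_H (98.2; 99.79 against matched lengths), or 1.82 in FMF_H relative to the median gene, and diverged there, with SDHA at 26.5 and 2.89 RPKM and RPLP0 at 223 and 446. Of the markers of leukocytes, fibroblasts, endothelium and erythroid cells 3 passed the filter, LCP1 (9.82, 11.8 and 18.3 RPKM), COL1A1 (0.96, 1.87 and 0.365) and KDR (1.44, 1.66 and 0.0904).

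In FMF_H most genes were lower than in the control while mitochondrially encoded genes were higher. A handful of genes taking most reads would leave the others alike once scaled. After median-ratio scaling 40.3% of the 10682 genes with at least 300 reads still differed by 1 or more. Such genes do not account for that spread. The scaling removes any common shift, so whether reads of few genes lowered the median gene (-0.94) stays open. Mitochondrial reads made up 6.94% of the control total and 30.4% of the FMF_H total. With mitochondrial genes left out and library sums made equal, the median gene of FMF_H against control lay at -0.98. Leaving them out thus did not raise it, and other abundant genes were not left out. Genomic DNA would add reads to silent genes. In 47 olfactory receptor genes, with 153 reads in the control and 37 in FMF_H, the FMF_H over control ratio was 0.227 (exact 95% interval 0.154 to 0.327). FMF_H thus had no excess of reads in them. Genes at 0 in every library were left out, so the 47 were not shown to be silent. Degraded RNA stays open for the trend with exonic length, where rho across 10190 genes was -0.114 (bootstrap 95% interval -0.132 to -0.0945), between the values fixed for either outcome. Introns are absent from mature RNA, so degraded RNA predicts little trend with genomic span, where rho was -0.214. That comparison was chosen after the values were seen. Because rho was 0.223 in FMF_L, a library close to the control, it does not decide on degraded RNA. A candidate explanation is less transcription of long genes, for which a rho of -0.15 or lower had been predicted, and -0.214 (-0.234 to -0.199) met it. It remains weakly backed, since rho was 0.223 (0.206 to 0.238) in FMF_L, as large with the opposite sign in a library close to the control, and the group of longest span was less lowered (-1.27) than the one before it (-1.35). Loss of short-lived precursors predicted a lower median for the 182 miRNA loci than for protein-coding genes of like expression. Their median was -0.48, above the range of random lists of such genes (-1.14 to -0.83). The explanation stays open, since the loci had a median of 74 bp and 3 reads in the control, too short for protein-coding genes of like length.

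Immediate early genes, snRNA loci and histone genes were higher in FMF_H. Less complete selection of polyadenylated RNA would not move immediate early mRNAs, which carry a poly(A) tail, yet their median was 1.97, above the range of random lists (-1.42 to 0.33). That is the value already reported for the same list, so it adds no separate evidence. For the snRNA loci that explanation may hold, since the median of snoRNA loci moved with them (0.27 over 136 loci, random lists -1.17 to -0.66). Of these snoRNA loci 43 were higher by at least 1 and 27 lower. The random lists were not matched on length, and loci with few control reads can pass the filter through FMF_H alone. Whether the treatment or the library preparation raised the snRNA and histone loci stays open.

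Cell cycle genes were lower in FMF_L and lower still in FMF_H. Counting error would put few of the 36 G2/M genes below the median gene, but 30 had an exact interval of the FMF_L over control ratio below it and 2 above. An unusual control library does not enter FMF_H against FMF_L, where the G2/M median was -2.53 (random lists -1.46 to -0.01). For the step from control to FMF_L, of -0.47, a control library with high cell cycle genes cannot be told apart from an effect of the treatment, because there is 1 control library. An effect of the treatment on both steps is thus a hypothesis that may be tested with replicate libraries.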
